A study of Homo sapiens with 9 samples.

How the data were processed

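RNA of 9 samples was hybridised to Affymetrix U133 Plus 2.0 arrays after biotin labelling. The growth protocol and the title name THP-1 cells and the source labels blood, and the samples were treated as THP-1. Groups were taken from the labels, with 3 arrays each for unstimulated, LPS and Q10+LPS cells. Per the labels' protocols, Q10 or vehicle was present for 24 h, the medium was then replaced, and LPS at 1 µg/ml was given for 4 h except in unstimulated cells. Sample labels of the cells without Q10 mention medium, and whether these cells received the vehicle is not settled here. The labels do not say whether same-group arrays come from separate cultures, so p-values measure the spread between these arrays, which may be partly technical.

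The deposited values are intensities per probe set on a linear scale, made with GCRMA per the submitters' processing notes. GCRMA corrects the background by probe sequence, normalizes arrays by quantiles and summarises the probes of a set. Its version and settings are not given in the sources used here. The linear scale was read from the values, which run from about 1.5 to 79161. No detection calls were used here. Because no value was below 1, the planned floor of 1 changed nothing, and log2 was taken. A background correction of this kind pulls dim probe sets to a common low level, so changes of genes that are near background in a group depend on it.

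The table held 54675 probe sets. By the platform annotation, 41097 have 1 gene symbol, 1801 have several and 11777 are not listed. Gene numbers of 41043 probe sets with 1 symbol were found in a RefSeq gene table (GRCh38.p14), and symbols were updated from it. Probe sets with several or no symbols and the 62 control probe sets were left out of the gene tests. For each of 19775 genes the probe set with the highest mean over the 9 arrays was kept, if it reached a log2 intensity of 5 on at least 3 arrays. This left 11162 genes. Genomic positions are not reported, since no build is tied to the values.

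Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on all 9 arrays, with 1 coefficient per group), with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. All tests are two-sided. Unadjusted p-values of single genes are limma's. Induced genes are those past the threshold with at least a 2-fold increase. Before the data were examined, the design, the alternatives, 34 gene lists with 798 genes and the rule for named genes were fixed. Of the list genes 612 were tested, and lists with at least 4 tested genes were compared with the other genes by camera with a preset correlation of 0.01, and with an estimated correlation as an alternative, adjusted over 33 lists. A further alternative, fry, tests whether the genes of a list move on balance 1 way and does not compare them with other genes. In the LPS comparison 14 lists were called with the preset correlation, 0 with the estimated correlation and 11 by fry. The stimulated genes as a set were chosen from the mean of both stimulated groups, which is uncorrelated with their difference when groups are of equal size.

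Named genes are the 10 with the largest rise and the 10 with the largest fall after LPS among genes past the threshold whose 3 values do not overlap between groups, the 10 per direction with the smallest p under Q10, the 14 induced genes with the smallest p for a lower value with Q10, and up to 4 members per list with the largest change. TNF, TLR4 and CD14 were added after their values were seen.

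The labels number the arrays 1 to 3 in each group, and the numbers were checked for pairing before calls were compared. Deviations from the group means correlated with r between 0.32 and 0.77 for all 9 same-number pairs, and between -0.67 and 0.11 for other pairs. All 9 arrays were closest to their own number in both other groups. The numbers were therefore taken to pair the arrays on the evidence of the data, as the labels do not say what a number stands for. The fit with the number as a block was set beforehand as an alternative to the main model, and its values are given where they change a call or move a count of genes or of a list by over 1.5 times.

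The scripts were tested on simulated arrays built from the real group means, replicate effects and spread, with 200 changed genes per draw for Q10+LPS against LPS among 11162 genes. The replicate effects put in were estimates that already hold noise of the arrays. Without the block this makes the simulated spread too wide and lowers recovery and counts of small p-values. Over 20 draws the fit without the block recovered 8.51% of genes changed 1.5-fold, 59.3% at 2-fold and 88.1% at 3-fold, and 0.241% of its calls were false. The blocked fit recovered 59.6%, 95.6% and 99.4%, with 4.93% false. A list shifted by 0.5 was found in 20 of 20 draws, and 1 unshifted list was called over all draws. The noise was drawn for each gene alone, so the 20 may overstate what is found where list members share noise. A further 100 simulated sets without a Q10 effect, and 100 without any effect, gave the values that shared arrays produce by chance. Alternatives covered the dim filter, a floor, quantile normalization, median centring, moderation, array weights, the arrays in the fit, the choice of probe set, the threshold, a plain two-sample statistic, the choice of induced genes, set tests and leaving out arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.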

Results

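Transcript levels were measured on 9 Affymetrix U133 Plus 2.0 arrays in cells that the growth protocol and the series title call THP-1, a human monocytic leukaemia cell line that is widely used as a model of monocytes. The source labels name blood instead, and the samples were taken to be THP-1 cells. The labels put 3 arrays in each of 3 groups. Cells of the Q10+LPS group were kept for 24 h with 10 µM oxidized ubiquinone (coenzyme Q10), a lipid that carries electrons in the mitochondrial respiratory chain, and then for 4 h with 1 µg/ml lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria that is sensed by TLR4. The LPS group received LPS without Q10, and the unstimulated group received neither. The median intensity over all probe sets lay between 23.5 and 24.5 on the 9 arrays. Correlations of log2 intensity between arrays of the same group lay between 0.967 and 0.992 across genes, which are not independent replicates. After removal of dim probe sets, 11162 genes were tested, and the number of arrays (n = 3 per group) limits the precision of each value. Changes are given on the log2 scale with the standard error of the limma fit, and levels as mean ± SD.

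The comparison of LPS with unstimulated cells asked which genes LPS induces, and it served as the positive against the negative control. The largest increases were in ELOVL7, a fatty acid elongase, with a log2 change of 7.65 ± 0.48, and in TNFAIP6, a secreted hyaluronan-binding protein, with 7.57 ± 0.39. TNFAIP6 stood at a log2 intensity of 5.58 ± 0.90 in unstimulated cells and 13.16 ± 0.24 after LPS. RASGRP1, a guanine nucleotide exchange factor for Ras, rose by 6.55 ± 0.11, the chemokine CCL4 by 6.36 ± 0.45 and the matrix glycoprotein THBS1 by 6.09 ± 0.38. The gap junction gene GJB2 rose by 5.66 ± 0.36, CT75 by 5.52 ± 0.15, the Notch coactivator MAML2 by 5.51 ± 0.39, the surface receptor SLAMF7 by 5.27 ± 0.15 and EBI3, a cytokine subunit, by 5.22 ± 0.29. The limma adjusted p of these 10 genes lay between 1.23e-08 for RASGRP1 and 8.53e-05 for MAML2. Other probe sets of the same gene gave smaller changes, down to 2.53 for THBS1, 1.67 for MAML2 and 0.39 for SLAMF7. Unstimulated means of 8 of the 10 were under a log2 intensity of 5, where the arrays give little signal over background, so the size of these changes rests on the background correction.

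**Figure D1:**
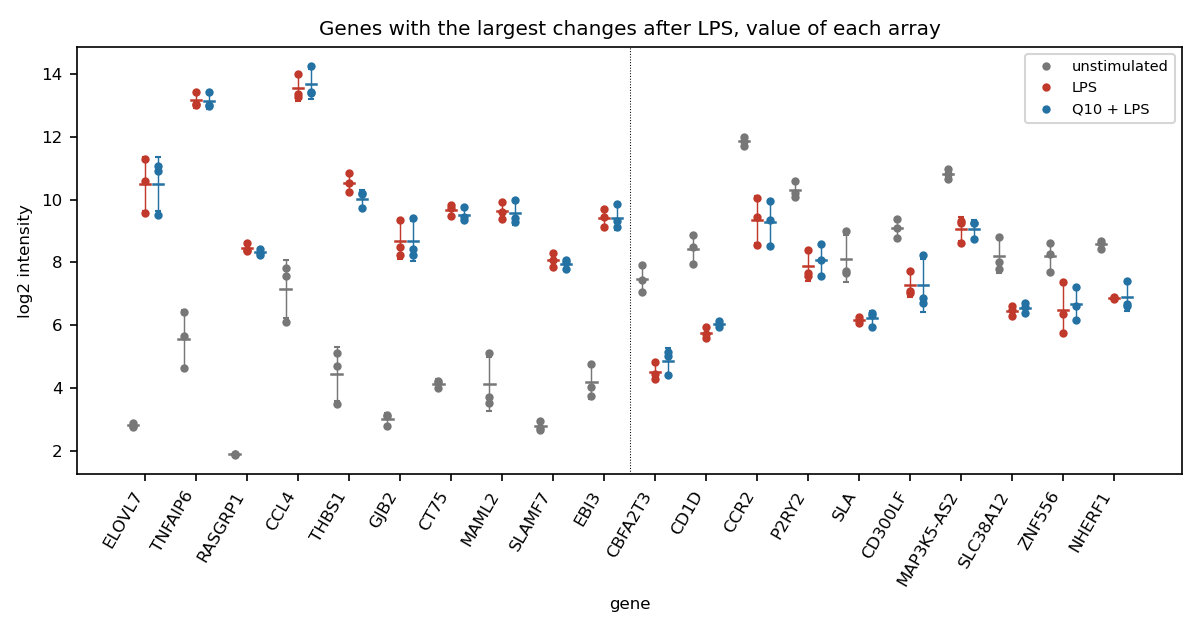
Log2 intensity (vertical axis) of the 10 genes that rose most after LPS (left of the dotted line) and the 10 that fell most (right) on each array; points are arrays, and bars with whiskers are the mean and SD of 3 arrays in unstimulated, LPS and Q10+LPS cells. TNFAIP6 stood at 5.58 ± 0.90 unstimulated, 13.16 ± 0.24 after LPS and 13.12 ± 0.24 after Q10 and LPS.

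The largest fall was in the transcriptional corepressor CBFA2T3, which fell from a log2 intensity of 7.47 ± 0.42 to 4.54 ± 0.28, a change of -2.94 ± 0.27 with adjusted p = 3.02e-04. The lipid-antigen-presenting molecule CD1D changed by -2.69 ± 0.21, the chemokine receptor CCR2 by -2.50 ± 0.42, the nucleotide receptor P2RY2 by -2.41 ± 0.30 and the adaptor SLA by -1.95 ± 0.33. The inhibitory receptor CD300LF changed by -1.80 ± 0.40, the antisense RNA MAP3K5-AS2 by -1.74 ± 0.22, SLC38A12 by -1.73 ± 0.25, the zinc finger gene ZNF556 by -1.70 ± 0.43 and the scaffold protein NHERF1 by -1.70 ± 0.20. All 10 passed the limma threshold, with ZNF556 closest to it (adjusted p = 0.0399).

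In all, 621 genes rose and 528 fell (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 376 rose and 144 fell by at least 2-fold. The median change of all tested genes was -0.07. With the replicate number as a block, 1268 genes rose and 1748 fell, among them all 1149 genes called without it. The counts fell to 359 and 156 without LPS array 3, and to 414 and 222 without LPS array 1. Without unstimulated array 2, 289 genes fell, and without the 3 arrays of number 3, a setting chosen after seeing the data, 114 rose and 13 fell.

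Cytokine and chemokine genes were among those that rose. Of 17 cytokine genes tested, 8 rose and none fell (10 adjusted over the list alone), led by EBI3, by the inflammatory cytokine IL1B with 4.31 ± 0.29, by IL23A with 4.16 ± 0.73 and by IL6 with 3.34 ± 0.44. TNF, which was chosen after its values were seen, rose by 1.44 ± 0.34 (limma adjusted p = 0.0301). Of 14 chemokine genes, 10 rose and none fell (11 adjusted over the list alone). CCL4, which attracts monocytes and T cells, rose 82.1-fold, CCL8 27.7-fold, the neutrophil attractant CXCL2 23.8-fold and the interferon-inducible CXCL10 21.7-fold. CCL4 and CXCL2 have near-identical relatives, so the assignment of their signal is uncertain. The median log2 change was 0.90 for cytokines and 3.28 for chemokines. In the camera test with a preset correlation, both lists stood above the other genes (adjusted p = 5.37e-08 and 3.09e-12), and with an estimated correlation the adjusted p was 0.245 for each.

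Genes of NF-kB, the transcription factor that LPS activates through TLR4, and of its feedback were among them as well. Of 26 tested, 12 rose and none fell, against 21 adjusted over the list alone and 21 with the replicate block. TNFAIP6 led the list, followed by IER3 with 3.73 ± 0.41, the kinase MAP3K8 with 3.22 ± 0.34 and NFKBIZ, an atypical IkB protein, with 3.01 ± 0.60. In the list of TLR4, its coreceptors and adaptors, 3 of 18 rose and none fell (4 adjusted over the list alone; 7 rose and 1 fell with the replicate block). These were the kinase IRAK2 with 3.36 ± 0.29 (1.35 by its other probe set), TAB2 with 1.08 ± 0.16 and TRAF3 with 0.65 ± 0.11, while the adaptor TICAM1 had 0.74 ± 0.27 (limma adjusted p = 0.114). TLR4 and its coreceptor CD14, chosen after their values were seen, had log2 changes of 0.09 ± 0.18 and 0.02 ± 0.52, which did not pass the test. The preset-correlation camera test called the NF-kB list (adjusted p = 1.63e-13) and the TLR4 list (adjusted p = 0.00227). With an estimated correlation the adjusted p was 0.245 and 0.331. With both the replicate block and an estimated correlation it was 0.0444 for the NF-kB list, the smallest of the 33 lists.

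All 40 tested genes of the type I interferon response had a higher mean after LPS, with a median log2 change of 1.99. Only 7 of them rose past the threshold over all genes, against 32 adjusted over the list alone and 39 with the replicate block. The guanylate-binding proteins GBP2 and GBP5 rose by 3.61 ± 0.41 and 2.93 ± 0.49. OAS3, an enzyme that senses viral RNA, and IFIT1, which binds viral RNA, had changes of 3.05 ± 1.14 and 2.99 ± 1.02 that missed the threshold (limma adjusted p = 0.129 and 0.101) and passed it with the block (adjusted p = 0.00506 and 0.00268). The levels of these genes differed between replicate numbers in each group. The median log2 intensity of the 40 genes on unstimulated arrays 1, 2 and 3 was 8.75, 6.54 and 8.15, on LPS arrays 10.77, 8.89 and 9.64, and on Q10+LPS arrays 10.45, 9.13 and 9.93. The difference between LPS and unstimulated arrays of the same number had a median of 1.93, 2.34 and 1.59. The camera test with a preset correlation called the list (adjusted p = 6.51e-15), and with an estimated correlation its adjusted p was 0.419.

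**Figure D2:**
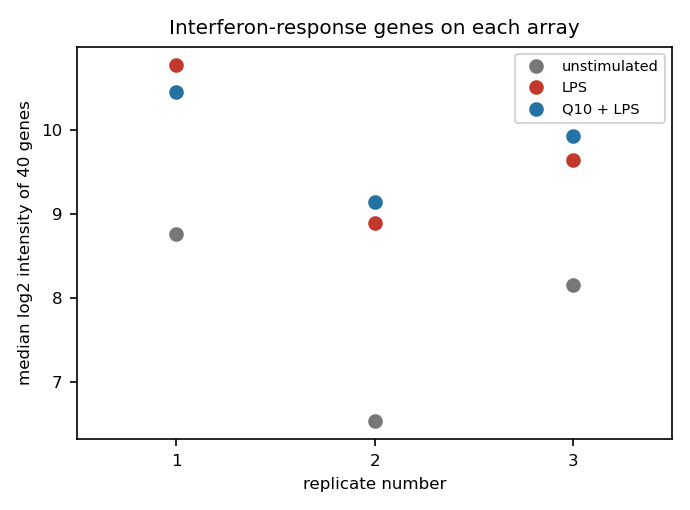
Median log2 intensity of the 40 tested interferon-response genes (vertical axis) on each of the 9 arrays, by replicate number (horizontal axis) and group. In each group the array with number 1 is highest and the array with number 2 lowest, for example 8.75 and 6.54 in unstimulated cells.

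Transcription factors of the immediate early response rose in 7 of 21 cases and none fell (8 rose and 1 fell adjusted over the list alone; 10 rose and 1 fell with the replicate block), including MAFF with 3.02 ± 0.52, the orphan receptor NR4A3 with 2.80 ± 0.73, ATF3 with 2.18 ± 0.56 and JUN, a subunit of AP-1, with 2.13 ± 0.43. Among phosphatases and other brakes on MAPK and cytokine signalling, 6 of 25 rose and 2 fell (7 and 3 adjusted over the list alone; 13 and 3 with the replicate block). The cytokine signalling inhibitor SOCS3 rose by 3.47 ± 0.31, and the MAPK phosphatases DUSP16, DUSP1 and DUSP2 by 2.59 ± 0.30, 2.25 ± 0.55 and 1.96 ± 0.27. Across the probe sets of a gene the change ran from 1.54 to 3.02 for MAFF, 0.82 to 2.18 for ATF3, 1.37 to 2.85 for JUN, 0.05 to 3.47 for SOCS3 and 0.03 to 2.25 for DUSP1. Among regulators of apoptosis, 4 of 23 rose and 1 fell (8 and 1 adjusted over the list alone; 8 and 2 with the block). The risen genes act both ways on cell death: BCL2A1 (3.91 ± 0.56) opposes it, and TNFSF10 (1.93 ± 0.33), BID (1.30 ± 0.14) and PMAIP1 (1.00 ± 0.14) promote it. The camera test with a preset correlation called the 3 lists (adjusted p = 1.47e-04, 1.99e-05 and 0.0143). With an estimated correlation the adjusted p was 0.559, 0.245 and 0.245.

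In the adhesion and costimulation list 9 of 20 rose and 1 fell (11 rose adjusted over the list alone; 11 rose and 2 fell with the replicate block), with SLAMF7 in front, then CD80, a ligand of CD28, with 4.92 ± 0.17, ICAM1 with 3.47 ± 0.39 and the PD-1 ligand CD274 with 3.30 ± 0.48. Across probe sets the change ran from 2.22 to 4.92 for CD80 and 1.58 to 4.10 for ICAM1. In the list of tissue factor, plasminogen system and proteases 5 of 13 rose and none fell. They included THBS1, SERPINB9, an inhibitor of granzyme B, with 3.75 ± 0.34, F3 (tissue factor), which starts coagulation, with 2.49 ± 0.27, and the elastase inhibitor SERPINA1 with 1.52 ± 0.26. Of 18 myeloid G protein-coupled receptors and their ligands, 7 rose and 1 fell (8 and 2 adjusted over the list alone). The histamine receptor HRH1 rose by 2.10 ± 0.16 and GPR84 by 2.16 ± 0.34, P2RY2 fell, and HCAR3 had 2.90 ± 0.94 (limma adjusted p = 0.086). The camera test with a preset correlation called the 3 lists (adjusted p = 1.04e-06, 1.51e-04 and 0.0115). With an estimated correlation the adjusted p was 0.245 for each.

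Of 22 targets of NRF2, the transcription factor of the antioxidant response, 10 rose and none fell (14 adjusted over the list alone), including OSGIN1 with 2.57 ± 0.32, the haem-degrading enzyme HMOX1 with 2.54 ± 0.43, and the aldo-keto reductases AKR1C1 with 2.39 ± 0.30 and AKR1C2 with 2.19 ± 0.32. In the list of metallothioneins and zinc transporters 9 of 11 rose and none fell. MT2A rose 7.97-fold, MT1H 3.95-fold, MT1E 3.86-fold and the zinc importer SLC39A8 3.21-fold, with log2 changes from 0.17 to 2.59 across its 5 probe sets. The metallothioneins and the AKR1C enzymes are near-identical families, so which member gave the signal is uncertain. In the glycolysis and hypoxia list 4 of 25 rose and none fell (6 and 1 with the replicate block). These included the peptide ADM with 4.26 ± 0.22, the glucose transporter SLC2A6 with 2.74 ± 0.41 and the glycolytic activator PFKFB3 with 1.49 ± 0.21, while SLC2A3 had 2.25 ± 0.85 (limma adjusted p = 0.131). The list's median was 0.06. The preset-correlation camera test called the 3 lists (adjusted p = 7.67e-11, 1.64e-10 and 0.00995), and with an estimated correlation the adjusted p was 0.286, 0.245 and 0.626.

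The other 19 lists were not called. In the list of ubiquinone biosynthesis 1 of 14 genes rose and 1 fell. These were HPD, an enzyme of tyrosine breakdown (1.57 ± 0.24), and COQ8A, an atypical kinase of the pathway (-0.77 ± 0.13). Complex I of the respiratory chain, which reduces ubiquinone, had 2 of 32 genes lower, NDUFS3 (-0.51 ± 0.13) and NDUFB10 (-0.50 ± 0.12). Complexes IV and V had 0 of 25. Among other ubiquinone-using enzymes and complexes II and III 3 of 20 rose, AIFM2 (1.21 ± 0.28), NQO1 (0.87 ± 0.23) and GPD2 (0.69 ± 0.12), and 1 fell. Of 24 antioxidant enzymes 2 rose, SOD2, the mitochondrial superoxide dismutase (2.98 ± 0.63), and GSR (0.93 ± 0.21), and 2 fell. NCF4 (-0.72 ± 0.15) was the 1 gene of 7 in the NADPH oxidase list that fell. In the inflammasome list IL1B rose while PYCARD (-1.26 ± 0.13) and NLRP3 (-0.95 ± 0.20) fell, out of 13. The prostaglandin synthase PTGS2 (2.56 ± 0.34) and TBXAS1 (1.02 ± 0.26) were the 2 of 13 that rose in the lipid mediator list. One of the 2 TBXAS1 probe sets had the opposite sign.

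Of 19 monocyte identity genes, CCR2, IRF8 (-1.29 ± 0.27) and CX3CR1 (-1.28 ± 0.22) fell and CEBPD (1.13 ± 0.15, and 2.45 by its other probe set) rose. SPP1 (2.45 ± 0.53) was the 1 of 11 macrophage differentiation genes that rose. Among 21 LXR and PPAR targets and partners 3 rose, including the cholesterol exporter ABCA1 (1.37 ± 0.21) and the lipid droplet protein PLIN2 (1.58 ± 0.39), and 4 fell, including RXRA (-1.19 ± 0.22). DNA replication had 2 of 25 genes lower, MCM2 (-0.63 ± 0.14) and MCM7 (-0.51 ± 0.11), against 8 lower and 1 higher with the replicate block. Of 13 p53 targets 2 rose, PLK3 (1.23 ± 0.28) and PMAIP1, and XPC (-0.71 ± 0.18) fell. DNAJB4 (1.60 ± 0.11) was the 1 heat shock gene of 13 that rose. None of 26 mitosis genes, 19 cholesterol synthesis genes, 21 endoplasmic reticulum stress genes, 13 housekeeping genes or 4 lymphocyte markers passed the threshold. The median log2 change was -0.20 for ubiquinone biosynthesis, -0.23 for DNA replication and 0.02 for housekeeping genes. With the replicate block, the genes that fell numbered 3 in ubiquinone biosynthesis, 5 in complex I, 3 among other ubiquinone-using enzymes, 5 among antioxidant enzymes, 6 in monocyte identity, 8 among LXR and PPAR targets, 3 in mitosis, 2 in cholesterol synthesis, 2 among p53 targets, and 1 each in complexes IV and V, endoplasmic reticulum stress, lipid mediators and macrophage differentiation. With the block, 4 antioxidant enzymes, 4 macrophage differentiation genes, 3 inflammasome genes, 2 heat shock genes, 1 cholesterol synthesis gene and 1 NADPH oxidase gene rose. Adjusted over the list alone, 4 antioxidant enzymes rose and 4 fell, 4 LXR and PPAR targets rose and 5 fell, 3 inflammasome and 2 macrophage differentiation genes rose, 5 monocyte identity genes fell and 0 complex I genes fell. For antioxidant enzymes, NADPH oxidase, other ubiquinone-using enzymes and heat shock proteins the median was below 0 and the mean above it.

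**Figure D3:**
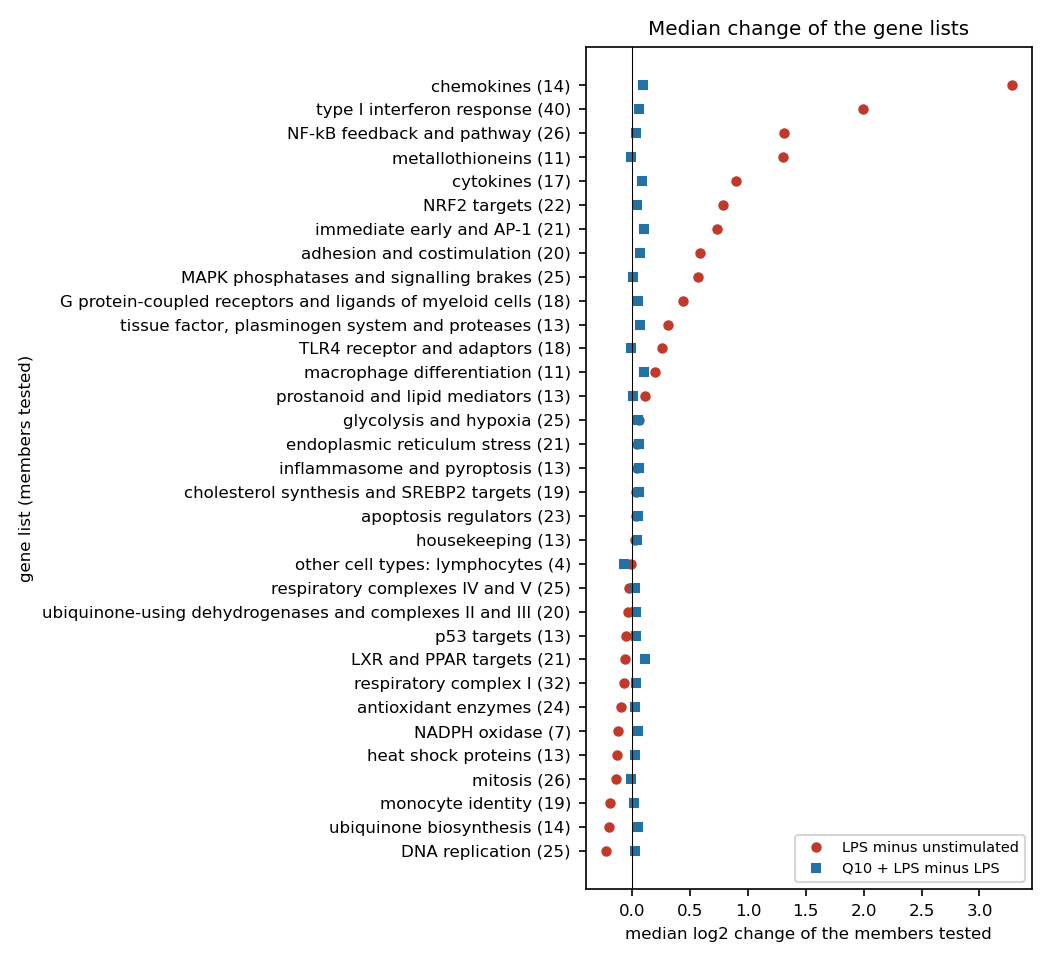
Median log2 change of the members tested (horizontal axis) for the 33 gene lists with at least 4 genes tested (vertical axis, number of members in brackets); circles are LPS minus unstimulated and squares Q10+LPS minus LPS. Chemokines have the highest median after LPS, 3.28, and 0.10 for Q10+LPS minus LPS.

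Cells pre-incubated with Q10 responded to LPS with many of the same genes. Against unstimulated cells, 564 genes rose and 402 fell in the Q10+LPS group (limma adjusted p under 0.05; 1150 and 1468 with the replicate block). TNFAIP6 stood at 13.12 ± 0.24 and CCL4 at 13.67 ± 0.48, against 13.16 ± 0.24 and 13.53 ± 0.40 after LPS without Q10. Of the genes called, 515 were higher and 350 lower in both comparisons, and 0 went in opposite directions. Independent lists would share 31.4 higher and 19.0 lower genes, and simulated arrays with no effect of LPS or Q10 shared 0. Without an effect few genes should pass in either comparison, so the 0 cannot show what shared arrays add when LPS acts. The 376 genes raised at least 2-fold by LPS had a median log2 change of 1.72 without and 1.74 with Q10, and the 144 lowered genes -1.23 and -1.13. Both sets were chosen by LPS against unstimulated cells, which favours larger changes there. The step from -1.23 to -1.13 can therefore not be read as an effect of Q10. The log2 changes of the 2 comparisons correlated across genes with r = 0.972 (0.50 in the simulation), and their covariance was 0.341 (0.0104 in the simulation). Both comparisons use the same 3 unstimulated arrays, so part of the excess over independent lists may come from these. Without Q10+LPS array 3 the counts were 336 and 114, without unstimulated array 2 428 and 193. Without Q10+LPS array 2, unstimulated array 3 and LPS array 3 the numbers that fell were 236, 247 and 242.

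**Figure D4:**
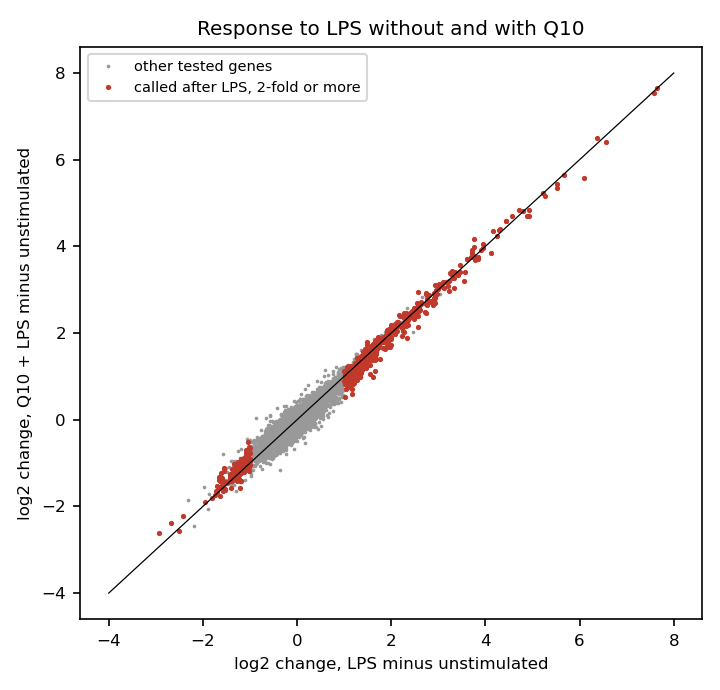
Log2 change of the 11162 tested genes after LPS (horizontal axis) and after Q10 and LPS (vertical axis), both minus unstimulated cells; red points are the 376 raised and 144 lowered genes called after LPS at 2-fold or more, and the line marks equal changes. The points lie along the line (r = 0.972 across genes), and the shared unstimulated arrays alone gave 0.50 in the simulation.

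The comparison of Q10+LPS with LPS asked which genes Q10 changes in stimulated cells, the question named by the title of the series. No gene passed the limma threshold in either direction, with or without the replicate block, and a plain two-sample statistic also called 0. The smallest adjusted p was 1.00 (0.999 with the block). At an unadjusted p under 0.05, 38 genes were higher and 79 lower, and with the block 165 were higher and 291 lower. Independent tests would give 558 in all. Simulated arrays with the replicate differences and without a Q10 effect gave 80.4 in all and 40.4 lower on average without the block, where none of 100 draws reached the observed 117 and 79. With the block they gave 552 in all and 276 lower, where all 100 draws reached the observed 456 and 21 reached the 291. Without the block the simulated numbers are too low by an unknown amount, since the replicate differences put in already hold noise of the arrays. No gene differed by 2-fold and 14 differed by more than 1.5-fold. The SD of the log2 differences over all genes was 0.14, and the median standard error 0.17. In simulated arrays, the fit without the block recovered 8.51% of genes changed 1.5-fold and 59.3% of genes changed 2-fold, and the blocked fit 59.6% and 95.6%.

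The genes with the smallest p are given as values and not as changes. The smallest p belonged to DUXAP10, a pseudogene transcript, with 10.14 ± 0.24 after LPS and 9.44 ± 0.09 with Q10 (log2 difference -0.71 ± 0.15, 95% interval -1.06 to -0.36). Its unadjusted limma p was 0.00146. The ranking, standard errors and p given here are of the fit without the block. With the block the smallest unadjusted limma p of any gene was 4.87e-04. The other differences on the lower side were -0.55 ± 0.14 for LCORL, -0.52 ± 0.13 for MIR3682, -0.51 ± 0.13 for the phosphate transporter SLC20A2, -0.54 ± 0.14 for ETNK1, -0.61 ± 0.17 for LANCL3, -0.59 ± 0.16 for MICOS10P1, -0.38 ± 0.11 for PRPF38B, -0.43 ± 0.13 for C1D and -0.34 ± 0.10 for CPEB4. On the higher side they were 0.69 ± 0.19 for CNPY4, 0.37 ± 0.11 for IL9R, 0.50 ± 0.15 for KLK15, 0.35 ± 0.10 for DDO, 0.29 ± 0.09 for TESK1, 0.37 ± 0.12 for RIN1, 0.42 ± 0.14 for the histone gene H2BC5, 0.53 ± 0.18 for DHRS1, 0.29 ± 0.10 for NSUN5P1 and 0.31 ± 0.11 for DDX27. The other DUXAP10 probe set past the intensity filter had the opposite sign (0.06), and so did 1 of the 5 of ETNK1. DUXAP10, MICOS10P1, NSUN5P1 and H2BC5 have near-identical copies, so their signal is uncertain.

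The series asks above all which LPS-inducible genes Q10 lowers. Of the 376 genes at least 2-fold higher after LPS, 0 were lower with Q10 past the limma threshold. At an unadjusted p under 0.05, 7 were lower and 0 higher (23 and 1 of 469 induced genes with the replicate block). The LPS arrays enter both comparisons with opposite sign, and simulated arrays without any Q10 effect gave 3.51 lower genes on average (26.5 with the block), while independent lists would share 2.66. The number was 2 without LPS array 3 and 19 without LPS array 2. When the induced genes were chosen by the mean of both stimulated groups, which is not tied to the difference between them, 4 were lower at that p (16 with the block). When they were chosen from Q10+LPS against unstimulated cells, 1 was. That choice uses the Q10+LPS arrays with the same sign as the difference, which works against lower genes. Across genes, the changes in the 2 comparisons had r = -0.23 (-0.12 in the simulation) and covariance -0.0195 (-0.0103 in the simulation).

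The 14 induced genes with the smallest p for a lower value are given as values. LANCL3 had a log2 difference of -0.61 ± 0.17 (95% interval -0.99 to -0.24), CPEB4, which regulates translation, -0.34 ± 0.10, TOP6BL -0.50 ± 0.20, LINC00597 -0.51 ± 0.22, SGTB -0.34 ± 0.15, the nuclear receptor coactivator NCOA2 -0.38 ± 0.16 and DSE -0.45 ± 0.20. In the fit without the block, the unadjusted p was under 0.05 for these 7 and not for the others. Those were ARAP2 (-0.58 ± 0.27), CPEB2 (-0.34 ± 0.16), MCTP1 (-0.28 ± 0.14), SAMSN1 (-0.28 ± 0.14), DNAJB4 (-0.21 ± 0.11), ENPP4 (-0.23 ± 0.12) and PSD3 (-0.33 ± 0.18). All 14 were lower in each of the 3 same-number pairs of arrays by the probe set kept, and none passed the adjusted threshold. The choice by small p in these same arrays favours genes that are lower in every pair. The pairs are therefore no separate evidence that a difference repeats. A further probe set had the opposite sign for SGTB (0.22), CPEB2 (0.07) and DNAJB4 (0.05).

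**Figure D5:**
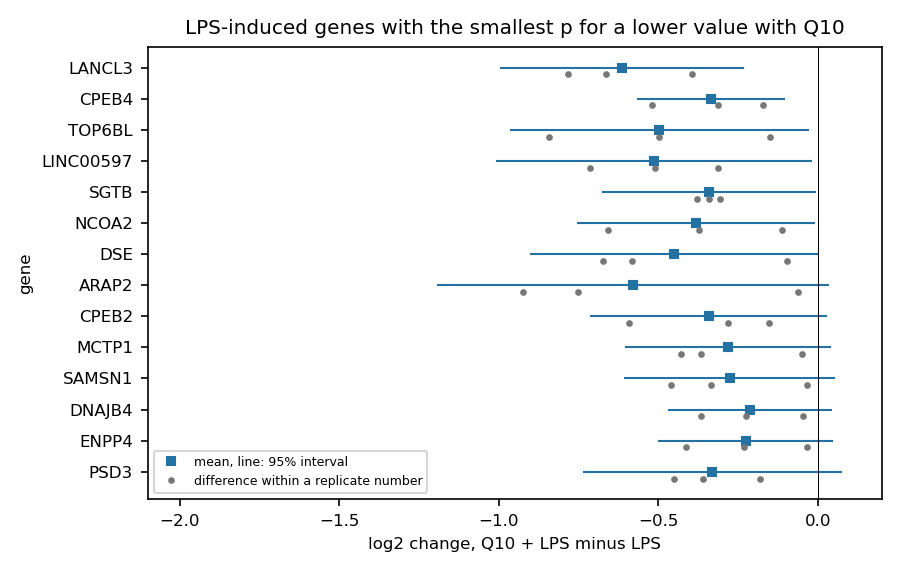
Log2 difference between Q10+LPS and LPS cells (horizontal axis) for the 14 LPS-induced genes with the smallest p (vertical axis); squares are the mean with its 95% interval from the limma fit without the block, and dots the differences within the 3 replicate numbers. LANCL3 is at -0.61 with an interval from -0.99 to -0.24, and none of the 14 passed the adjusted threshold.

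As a set, the 409 genes raised in the mean of the stimulated groups had a median difference of -0.0023 between Q10+LPS and LPS (207 lower, 202 higher), where all genes had 0.020. The camera test with a preset correlation placed them below the other genes (p = 0.0109), and with an estimated correlation the p was 0.543. Within replicate numbers 1, 2 and 3 their median was -0.079, 0.0028 and 0.037. The 154 lowered genes had a median of 0.064 (48 lower, 106 higher), with p = 0.0411 preset and p = 0.595 with an estimated correlation, and 0.24, 0.016 and -0.054 within the numbers. In settings chosen after seeing the data, with the sets chosen anew, the medians were 0.030 and -0.022 without replicate number 1, -0.026 and 0.080 without number 2, and -0.052 and 0.092 without number 3. The preset-correlation camera p was 0.740 and 0.215 without number 1, where neither set was called. It was 0.00601 and 0.00692 without number 2, and 1.64e-06 and 4.49e-05 without number 3. With the replicate block on the 409 and 154 genes, the preset-correlation camera p was 0.0180 for raised and 0.0314 for lowered genes, and with an estimated correlation it was 0.186 and 0.502. When the raised set was also chosen anew in the blocked fit, its median was 0.0071 and the preset p 0.0555. The raised median was above 0 without LPS array 1 (0.066), without Q10+LPS array 2 (0.11) and without unstimulated array 1 (0.0079), and it missed the threshold in the first and last of these. Without any 1 of the other arrays it lay further below 0, from -0.012 without unstimulated array 3 to -0.086 without Q10+LPS array 1 and -0.15 without LPS array 2. The lowered median was further above 0 without LPS array 2 (0.16) and without Q10+LPS array 3 (0.17). It was below 0 without Q10+LPS array 1 (-0.059) and array 2 (-0.022), and it missed the threshold without Q10+LPS array 2, without LPS array 3 (0.0093) and without unstimulated array 1 (0.048).

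None of the 33 gene lists was called under Q10, with the smallest camera adjusted p at 0.860 (0.732 with the replicate block), and no member of any list passed the threshold. Cytokines had a median of 0.08, NF-kB genes 0.04, interferon-response genes 0.06, NRF2 targets 0.04, ubiquinone biosynthesis 0.05 and complex I 0.03. IL1B had a log2 difference of 0.08 ± 0.29 (95% interval -0.58 to 0.75), IL6 0.05 ± 0.44 (-0.95 to 1.05) and CCL4 0.14 ± 0.45 (-0.87 to 1.16), intervals of the fit without the block. With the replicate block the intervals were -0.57 to 0.74, -0.60 to 0.70 and -0.54 to 0.82, and with either fit they hold a rise of 1.5-fold. A fall of 1.5-fold lies within the IL6 interval of either fit and the CCL4 interval without the block. It lies just outside the IL1B intervals and the blocked CCL4 interval. Within numbers 1, 2 and 3 the differences were 0.02, 0.08 and 0.15 for IL1B, -0.03, -0.06 and 0.25 for IL6, and 0.24, 0.06 and 0.12 for CCL4. Leaving out single arrays gave list calls under Q10, but it breaks a pair, so these calls mix Q10 with differences between numbers. Without LPS array 1, 10 lists were higher and 2 lower. Without Q10+LPS array 1, 2 were higher and 3 lower. Without LPS array 2, 1 was lower, and without Q10+LPS array 2, 1 was higher. Leaving out all 3 arrays of a number, chosen after seeing the data, gave 0.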

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

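Probe sets without a single gene symbol took no part in the gene tests, and they were examined because they carry signal that no comparison above uses. Of these, 4758 passed the intensity filter, and 201 were higher and 81 lower with LPS than in unstimulated cells (limma, adjusted over all probe sets past the filter). At 2-fold or more, 114 were higher and 22 lower, with a largest log2 change of 5.21.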

How the results depend on the processing

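The setting that left out all arrays of a number, and the block combined with the stimulated mean, were chosen after seeing the data. The cause of each shift was not tested unless the setting itself shows it. Under each alternative other than the looser threshold, 0 genes passed in Q10+LPS against LPS; with an unadjusted p under 0.05 and 1.5-fold in place of the adjusted p, 2 were higher and 6 lower, 2 induced genes were lower (17 at p alone), and 664 genes fell in Q10+LPS against unstimulated cells. With the replicate block, 1268 rose and 1748 fell after LPS, 1150 and 1468 after Q10 and LPS, and 23 induced genes were lower and 1 higher with Q10 at unadjusted p. The lists called stayed at 14 and 0. On the same genes, both sets were still called under Q10 with the preset correlation and neither with an estimated correlation or fry, and the raised set chosen anew in the blocked fit was not called. Block and stimulated mean together gave 16 and 2. Array weights gave 1908 and 2354, 1316 and 1547, and 14 and 1, but the weights did not converge and gave unstimulated array 3 a weight of 14.3. A plain two-sample statistic, with fewer degrees of freedom, called 148 and 50 after LPS and 86 and 25 after Q10 and LPS. Counting probe sets singly, which tests more features, gave 1130 and 911 higher and 22 induced ones lower with Q10. Fitting only the groups compared, which has fewer arrays, gave 168 lower after Q10 and LPS and 1 induced gene higher with Q10. Choosing induced genes from Q10+LPS, which works against lower genes, gave 1 lower, and from the stimulated mean 4.

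The median of the raised genes under Q10, -0.0023, was above 0, with the set chosen anew in each setting, under quantile normalization (0.0012), the replicate block (0.0071, against -0.0023 on the same genes), the mean of a gene's probe sets (0.0079) and a set chosen from Q10+LPS (0.0090). The camera test compares the set with the other genes and not with 0. The median of all genes was 0.020 in the main fit and 0.024 under quantile normalization, above that of the raised genes. With the preset correlation the raised set was still called under quantile normalization and with the mean of a gene's probe sets. It was not called with the block or when chosen from Q10+LPS. With the choice from Q10+LPS the lowered genes had 0.033 and with no dim filter 0.052, and neither passed. A set chosen from LPS against unstimulated cells gave -0.025 for raised and 0.093 for lowered genes, and both passed. That choice uses the LPS arrays with opposite sign, which favours this direction. A choice from Q10+LPS uses the Q10+LPS arrays with the same sign, which works against it. With an estimated correlation or fry, neither set passed at -0.0023 and 0.064. No filter called 1 list lower after LPS, and an estimated correlation called 0 higher.

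Leaving out arrays, singly or by number, gave 114 to 640 higher and 13 to 576 lower after LPS and 96 to 529 and 8 to 350 after Q10 and LPS; the lowest values came without number 3, and single arrays gave at least 359, 156, 336 and 114. It gave 0 to 19 induced genes lower and 0 to 1 higher with Q10, and medians from -0.15 to 0.11 for raised and -0.059 to 0.17 for lowered genes. Lists higher after LPS numbered 13 to 15 and lower 0 to 2; under Q10 they numbered 0 to 10 and 0 to 3. The list medians under Q10 ran from -0.35 to 0.44 for interferon genes, -0.26 to 0.41 for immediate early genes, -0.17 to 0.21 for signalling brakes, -0.20 to 0.17 for mitosis and -0.11 to 0.13 for DNA replication. Leaving out 1 array breaks a pair, so these shifts mix Q10 with differences between numbers. Median centring moved the share of higher genes after LPS from 54.0% to 61.7%. Of 5862 values of named genes after LPS under the alternatives, 325 lost and 146 gained the threshold. Genes near the intensity filter have little signal over background, and their changes are the least certain.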

Other observations

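The tests on the interferon genes, the left-out replicate numbers and the small p-values were chosen after the results were seen. Values of other gene groups by replicate number are given here. Between numbers 1 and 2, with group in the model, 1391 genes were higher and 1527 lower on number 1 (limma adjusted p under 0.05). Mitosis genes had a median log2 difference of -0.68, DNA replication genes -0.36 and complex I genes -0.27, while interferon-response genes had 1.64, immediate early genes 0.89, chemokines 0.80, NF-kB genes 0.60 and macrophage differentiation genes 0.58. The preset-correlation camera test called these 8 lists, with adjusted p from 3.24e-23 for interferon genes and 3.97e-12 for mitosis to 6.18e-04 for chemokines and macrophage differentiation. It called further lists too, such as adhesion and costimulation (median 0.66, adjusted p = 2.33e-04), cytokines (0.51, 0.00106), signalling brakes (0.55, 0.00163) and metallothioneins (-0.37, 0.0168). With an estimated correlation none of the 33 lists was called, and the adjusted p of the first 8 lay between 0.169 and 0.246.

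The interferon-response genes were lower on number 2 than on number 1 in each group. None of 10000 random lists of like size and expression had as large a median (share 0.0001, the smallest they can give). The list was picked after its difference was seen, and normalization by quantiles leaves little shift common to all genes (median -0.020). The random lists therefore cannot decide on an array-wide difference, and 1391 genes were higher and 1527 lower on number 1. Values near background are argued against, since the 31 members with a mean log2 intensity of 8 or more had a median difference of 1.60. The median of all 40 was 1.64. The standard error of the mean over the 31 genes was 0.11. It treats genes of the same arrays as independent and does not measure the spread between arrays. A state shared by the samples of a number and handling on a shared day stay open as candidate explanations. That 40 of 40 genes were higher on number 1 in all 3 groups restates the pattern and decides neither, and no biological explanation was tested.

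More induced genes were lower than higher with Q10 at unadjusted p (7 and 0). Noise of the shared LPS arrays may account for the number that were lower, since 5 of 100 simulated sets without a Q10 effect had as many, and 78 of 100 had the 23 of the blocked fit. It did not give the imbalance of the blocked fit, where 1 induced gene was higher. All 100 simulated sets had at least as many (17.6 on average). Nor did it give the covariance across genes of LPS against unstimulated cells with Q10+LPS against LPS. This was -0.0195, and all 100 sets were less negative (-0.0103 on average). The simulated sets leave out noise shared between genes. The imbalance, the covariance and a small Q10 effect that repeats between numbers therefore stay open. The 20 raised genes lowest with Q10 in the other numbers had medians of -0.25, -0.054 and -0.098 in numbers 1, 2 and 3 when each was left out, below the 5th percentile of random choices (-0.19, -0.059 and -0.053) in 2 of 3. Picking the lowest genes favours genes with a wide spread or with shared noise. The random choices were not matched for these, so the values cannot decide whether a difference repeats. The covariance of Q10 differences with the change in the mean of both stimulated groups was -0.0353 in number 1, -0.00033 in number 2 and 0.0068 in number 3.

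The comparison of Q10+LPS with LPS had 117 genes at unadjusted p under 0.05, where independent tests would give 558. Differences between numbers that widen the spread within groups are a candidate cause of the gap to 558, since the number rose to 456 with the replicate number in the fit, and simulated arrays with these differences and no Q10 effect gave 80.4 without and 552 with it. Against these the observed number lies above all 100 draws (at most 108) without the block and below all of them with it. The simulated arrays leave out noise shared between genes. Without the block their spread is also too wide, since the replicate differences put in already hold noise of the arrays. The excess of the first and the shortfall of the second therefore stay open. No biological explanation was tested for them.

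With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. LPS against unstimulated cells gave 1149 genes and other splits at most 0 (1 split as large, the real split). Q10+LPS against unstimulated cells gave 966 and other splits at most 0 (1 split as large). Q10+LPS against LPS gave 0 in each of the 10 splits. With the block, the 4 splits that part all pairs gave 3016, 2618 and 0 for the real split, and 0 for the others. In both comparisons with unstimulated cells, each other split mixes stimulated and unstimulated arrays within its groups. A large LPS effect then widens the spread within groups and lowers the calls. The 0 of these splits therefore cannot show that the calls are specific to the real split. The camera lists did not single out the real split: 14 lists after LPS against at most 18 elsewhere (5 of 10 splits as large), and 0 under Q10 against at most 21 (all 10 as large). Under Q10, the 6 splits that keep a pair on 1 side called 3 to 21 lists and those that part all pairs at most 2, which points to a structure by number. After LPS no such contrast was seen, with 4 to 18 lists for splits that keep a pair and 5 to 16 for the others that part all pairs. For induced genes lower with Q10 at unadjusted p, the real split gave 7 and others up to 153 (7 splits as large), but at most 1 where all pairs were parted. The set p of raised genes was 0.0109, against a lowest of 2.11e-15 elsewhere (8 splits as small) and 6.81e-06 where all pairs were parted. For lowered genes it was 0.0411, against 9.64e-19 (8 splits as small) and 3.63e-05.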
